A study of Mus musculus with 12 samples.

How the data were processed

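Poly(A) RNA of gastrocnemius muscle from WT mice and from TG mice with liver-specific E4BP4 overexpression was sequenced in 12 libraries, 3 in each of 4 groups (WT and TG at ZT0 and ZT12). Per the labels, total RNA was taken with a column kit, poly(A) RNA was selected, and libraries were made with an unstranded kit, so that reads of overlapping genes on opposite strands cannot be told apart. The mice were kept in a 12 h light and 12 h dark cycle on chow. The labels give no sex, no batch and no day of collection.

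The submitters' processing notes name bcl2fastq, STAR, HOMER 4.11.1 and DESeq2 on mm10. The deposited TPM table, 1 line per gene for the 12 libraries, holds transcripts per made by the authors for 10475 genes. Each listed gene has at least 1.0 TPM in WT ZT0 replicate 1, and 134 of them are at 0 in some other library, so the authors chose the listed genes by that library. Per the file headers, the 2 further tables were made with HOMER (exon reads per gene, FPKM, then a differential expression step) for the 6 libraries of each time alone. Their deposited per-library values are headed FPKM but are log2 values drawn towards each gene's mean. The same tables hold the authors' log2 fold change, p-value and adjusted p-value per gene, and the length in bases of each gene's transcript. Coordinates were taken from these files on mm10. Of the 10475 names, 10246 were found in GENCODE M21.

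The plan, fixed before the data were examined, assumed counts and a quasi-likelihood test of them. The files used here hold no counts, so its written fallback was used: limma 3.58.1 (trend) in R 4.3.3 on log2(TPM + 1), with a mean for each of the 4 groups in 1 fit of the 12 libraries. Contrasts were TG against WT at each time, ZT12 against ZT0 in each genotype, and the interaction. Genes with at least 1 TPM in at least 3 libraries were tested (10415), and calls needed a Benjamini-Hochberg (BH) adjusted p under 0.05. An additive model of genotype and time over the 12 libraries was added after the first results were seen. A replicate block was not part of the main model: among 18 pairs of libraries with the same replicate number, the correlation of what the groups left over ranged from -0.35 to 0.29, with a median of 0.06 against -0.02 for different numbers, and 5 of 12 libraries were closest to their own number. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

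The depth is not stated in the files. TPM times transcript length gave whole numbers (within 0.1 read, judged for values under 500 reads) at 1 scale per library for 99.96 to 99.99% of the values. In units of 1e+06, the reads recovered this way summed to 9.21, 13.1 and 11.5 in WT ZT0, 10.8, 10.4 and 11.5 in TG ZT0, 20.1, 17.7 and 20.2 in WT ZT12, and 13.1, 15.8 and 15.8 in TG ZT12. Reads of unlisted genes are not in these sums. The 10 highest genes took 30.1 to 39.0% of the listed TPM. Median TPM ran from 4.96 in TG ZT12 replicate 1 to 9.26 in WT ZT0 replicate 2. The median correlation of log2 values with the other libraries was 0.945 for WT ZT0 replicate 2 and 0.975 to 0.985 for the others. The standard error of the median gene was 0.19 within 1 time or genotype.

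Gene lists and cell type markers were fixed before the data were examined: core clock, muscle atrophy, autophagy and lysosome, glucocorticoid response, IGF1, GH and insulin signalling, fatty acid oxidation and PPAR targets, glucose uptake and glycolysis, mitochondrial respiration, slow fibre, fast fibre, myogenesis and regeneration, denervation and neuromuscular junction, integrated stress response, lipid and sterol synthesis, interferon response, heat shock and temperature response, extracellular matrix, immediate early, and markers of adipocytes, endothelium, macrophages, neutrophils, red cells, fibro-adipogenic cells, Schwann cells, smooth muscle, lymphocytes and hepatocytes, and sex-linked genes. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry (a directional test, and a mixed test for changes either way), BH over the lists of a contrast. Named genes were Nfil3, the 10 highest and 10 lowest log2 fold changes among called genes whose groups did not overlap (the 10 smallest p where fewer than 5 genes were called), and up to 4 called members of each list. Other genes are said to have been chosen after their values were seen. The values of 1 marker gene are not reported here.

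Alternatives were median-of-ratios and upper-quartile scaling, no filter, a stricter filter of 5 TPM, pseudocounts of 0.1 and 5, the 2 groups alone, the replicate block, the 10 highest genes removed, and each library left out in turn. Added after seeing the data were limma-voom on recovered reads, quantile normalization, the fit without WT ZT0 replicate 2 and TG ZT12 replicate 1, a haemoglobin covariate, a covariate of log2 depth, limma on the deposited log2 tables, and list tests without WT ZT0 replicate 3. Planned tests of counts, such as the quasi-likelihood test, were left out because the files hold none. Of tests made for counts, only limma-voom was run on the recovered reads. Array weights per library were tried and dropped, since their fit did not converge. The limma test was checked on simulated data with 200 changed genes in 10 runs per contrast: it found 9.25 to 14.2% of 1.5-fold, 81.0 to 83.0% of 2-fold and 96.2 to 97.6% of 3-fold changes within 1 time or genotype, and 65.0 to 65.9%, 96.0 to 96.1% and 99.1 to 99.5% in the additive model. Changed genes were drawn only from those with a mean level of at least 5 TPM on the log2 scale. The shares thus do not cover lower genes. Changes were added in full on the log2(TPM + 1) scale, where a real change of TPM is smaller, so these shares flatter the test. The noise was drawn independently for each gene, and correlated noise was not simulated.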

Results

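Gastrocnemius muscle (a calf muscle of the hind limb) of 8-week-old C57BL/6 mice was profiled by poly(A)-selected RNA sequencing in 12 libraries. Wild-type (WT) mice were compared with transgenic (TG) mice in which E4BP4, a transcriptional repressor linked to the circadian clock and encoded by Nfil3, is overexpressed in the liver alone. Muscle was taken at Zeitgeber time (ZT) 0, when the lights went on, and at ZT12, when they went off, with 3 libraries in each of the 4 groups. That each library came from a separate mouse is as far as the labels can be read. The deposited table held transcript abundances (TPM) for 10475 genes, of which 10415 were tested. The files state no depth. The TPM values became whole numbers of reads at 1 scale per library, which put the reads in the listed genes, in units of 1e+06, at 9.21 to 13.1 at ZT0 and at 13.1 to 20.2 at ZT12. Log2 depth was correlated with time (r = 0.85), and the ranges of the 2 times met only at 1 library each. At ZT12 the depth also differed by genotype, at 17.7 to 20.2 in WT and 13.1 to 15.8 in TG in the same units. At these depths 1 read on a transcript of 1 kb stood for 0.0411 to 0.0895 TPM. Every gene of the table had at least 1.0 TPM in WT ZT0 replicate 1, so genes silent in that library were missing from all comparisons of TPM. Genes silent there and active in TG or at ZT12 could not appear, while genes that went silent could. Counts of higher and lower genes can lean towards lower for this reason.

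The first question was whether E4BP4 overexpression in the liver went with a different muscle transcriptome at lights on. Muscle Nfil3 itself (chromosome 13, 52967209 to 52981039, mm10) stood at 17.2 ± 1.42 TPM in WT and 16 ± 3.72 TPM in TG at ZT0 (mean and SD, n = 3 each), a log2 fold change of -0.11 with a standard error of 0.31. The differences with the smallest p included 3 neighbours on chromosome 19. Prdx5, a peroxiredoxin that removes peroxides, stood at 143 ± 6.66 TPM in WT and 66.9 ± 4.08 TPM in TG, Trmt112, a methyltransferase cofactor, at 22.6 ± 2.08 and 10.4 ± 0.797 TPM, and Rps6ka4, a stress-activated kinase, at 5.83 ± 1.94 and 2.23 ± 0.411 TPM. Esrra, a nuclear receptor of mitochondrial genes that lies beside Trmt112 and was picked after its values were seen, stood at 60.6 ± 3.19 and 32.6 ± 4.32 TPM. None of these differences passed the test: limma called 0 of 10415 genes at a Benjamini-Hochberg adjusted p under 0.05. With limma, 117 genes had an unadjusted p under 0.05 where chance gives 521. Fewer small p than chance gives is no evidence that the genotypes are alike. The same holds for the genotype comparisons below. With limma, the time comparisons within 1 genotype also gave fewer than chance, 484 in WT and 368 in TG. The cause was not tested. Between genotypes at ZT0 the smallest adjusted p was 0.998 with limma. Limma-voom on reads recovered from the TPM values called 0 genes as well, with 125 at an unadjusted p under 0.05.

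The other genes of smallest p at ZT0 were Mir6988, Snord47, Rpl9, Mir6911, Fau, Mir7092 and Nnmt, with log2 fold changes from -1.88 for Mir7092 to -0.58 for Fau. Fau and Rpl9 encode ribosomal proteins, and Nnmt encodes nicotinamide N-methyltransferase. Mir6988 was listed at 0 TPM in all 3 TG ZT0 libraries and at 1.33 ± 0.187 TPM in WT. It spans 6051334 to 6051392, so that 1 read stands for far more TPM than on a 1 kb transcript. Its WT values and its rank thus rest on very few reads. The selection of genes required such reads in WT ZT0 replicate 1. The other Mir and Snord genes named are similarly short and rest on few reads. Mir6988 (start 6051334) and Fau (start 6057888) also lie on chromosome 19; Fau stood at 6.66 and 4.07 TPM in WT and TG at ZT0, and at 3.61 and 3.52 TPM at ZT12. Poly(A) selection does not capture mature small RNAs, and reads at such genes cannot be told apart from those of overlapping transcripts. Among the gene lists, the 11 tested interferon response genes all stood lower in TG, with a median log2 fold change of -0.63, and the median of the 12 immediate early genes was -0.42. Of the 23 mitochondrial respiration genes, 19 stood higher, with a median of 0.05 against a median of -0.10 over all genes. No member of any list was called over all genes or when adjusted over the list alone. Camera with its preset correlation called 11 lists: mitochondrial respiration (adjusted p = 6.48e-06 by camera, and adjusted p = 0.557 with an estimated correlation), interferon response (4.48e-05 and 0.687), fibro-adipogenic markers (0.000387 and 0.511), fatty acid oxidation (0.00142 and 0.687), fast fibre (0.00142 and 0.242), slow fibre (0.00309 and 0.687), glycolysis (0.00485 and 0.687), glucocorticoid response (0.0106 and 0.687), Schwann cell markers (0.0106 and 0.687), denervation (0.0209 and 0.687) and immediate early (0.0231 and 0.687). Interferon response and immediate early were lower relative to other genes and the other 9 were higher; the denervation genes had a median of -0.05 and a mean of 0.02, and the fatty acid oxidation genes a median of 0.06 and a mean of -0.02. WT ZT0 replicate 2 stood 1.64 above the 12-library mean in interferon genes and 0.51 above it in immediate early genes on the log2 scale. Without that library and TG ZT12 replicate 1, camera called 2 lists, slow fibre (adjusted p = 0.00293) and fibro-adipogenic markers (adjusted p = 0.0435). Relative to the 12-library mean, the slow fibre genes stood at -1.79 in WT ZT0 replicate 3 against 0.03 and 0.91 in the other WT ZT0 libraries. Without replicate 3 camera did not call them at ZT0 (adjusted p = 0.907). Fitted with these 6 libraries alone, limma called 1 gene, Prdx5 (log2 fold change -1.09, adjusted p = 0.0192, lower in 3 of 3 TG libraries), and Mir6988 alone was called when TG ZT12 replicate 3 was left out.

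**Figure D1:**
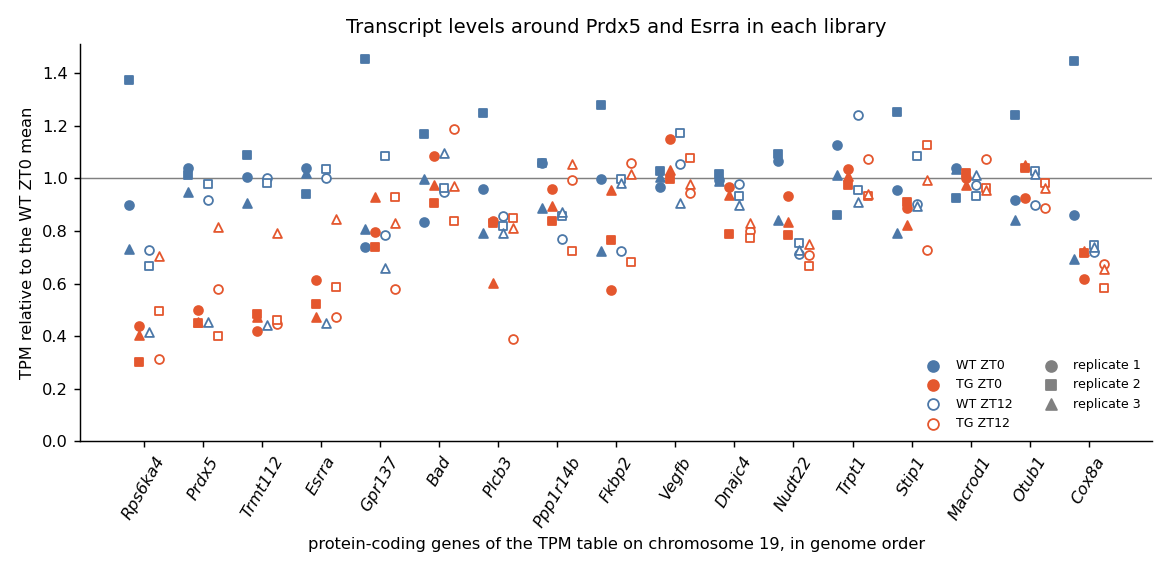
TPM of 17 protein-coding genes on chromosome 19 (mm10), from Rps6ka4 to Cox8a, in each of the 12 libraries, divided by the mean of the WT ZT0 libraries (1 is the WT ZT0 mean). Rps6ka4, Prdx5, Trmt112 and Esrra lie at 0.382 to 0.538 of WT in the TG ZT0 means, and the 13 genes beyond them at 0.686 to 1.06.

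At lights off the same comparison asked whether the TG muscle differed at the start of the dark phase. Every TG library of ZT12 was shallower than every WT library of ZT12, so depth and genotype cannot be told apart here. Nfil3 stood at 11.8 ± 3.79 TPM in WT and 13.5 ± 6.65 TPM in TG (n = 3 each), a log2 fold change of 0.13 with a standard error of 0.31. The genes of smallest p lay lower in TG, among them Abi3bp (log2 fold change -0.54), the secreted BMP antagonist Nbl1 (-0.49), the tetraspanin Cd9 (-0.50), the IGF-binding Igfbp6 (-0.52) and the receptor Tnfrsf19 (-0.54). The clock-linked repressor Bhlhe40 stood at 43.2 ± 5.69 TPM in WT and 30.1 ± 5.74 TPM in TG (log2 fold change -0.52). The remaining genes of smallest p were Mir7672 (-1.18), Pdgfrl (-0.54), Snord47 (-1.46) and Arl4d (-0.52). Limma called 0 of 10415 genes, with 99 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00, and limma-voom also called 0, with 191 at an unadjusted p under 0.05.

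No list member was called at ZT12 over all genes or when adjusted over the list alone. The 17 extracellular matrix genes (median -0.26), 7 Schwann cell markers (median -0.47), 5 smooth muscle markers (median -0.39) and 5 fibro-adipogenic markers (median -0.26) stood lower in TG. Of the immediate early genes, 11 of 12 stood higher (median 0.16). The median over all genes was -0.07, and the matrix genes ranged from -0.52 to -0.005, so that the sign of the least of them rests on the scaling. Camera called 7 lists at the preset correlation: immediate early (adjusted p = 3.5e-05 by camera, and adjusted p = 0.485 with an estimated correlation), Schwann cell (3.5e-05 and 0.485), extracellular matrix (4.8e-05 and 0.687), fibro-adipogenic (5.23e-05 and 0.426), smooth muscle (0.00139 and 0.485), fast fibre (0.0225 and 0.426) and denervation (0.0268 and 0.687). Immediate early, fast fibre and denervation were higher relative to other genes and the other 4 were lower, and the denervation median was -0.03 against a mean of 0.04. TG ZT12 replicate 1 held the lowest Schwann cell level of the 12 libraries, 1.27 below their mean on the log2 scale. Without that library and WT ZT0 replicate 2, camera called 0 lists at ZT12. Limma then called 2 genes, S100a4 (log2 fold change -0.90, adjusted p = 0.0446) and Crip1 (-0.77, adjusted p = 0.0446), each lower in TG. The deposited log2 table of ZT12, tested with limma after the other results were known, gave 39 calls (5 higher, 34 lower) over all 12930 genes with signal and 18 calls (2 higher, 16 lower) over the genes of the TPM test. The changes of the 39 genes were at most 0.0142 on a log2 scale drawn towards each gene's mean, and limma called 0 of the 18 tested from TPM.

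Whether the TG effect differed between the 2 times was asked with the interaction of genotype and time. The interaction carries the depth difference between the genotypes at ZT12. Dcn (decorin), Serpinf1, Smoc2 and the IGF-binding Igfbp6 had interaction values of -0.49, -0.62, -0.46 and -0.73, being lower in TG at ZT12 and not at ZT0, and Atp6v1g2, a subunit of the proton pump, had a value of 0.79. Decorin stood at 197 ± 16.2 TPM in WT and 232 ± 16.4 TPM in TG at ZT0, and at 259 ± 12.7 and 217 ± 23.4 TPM at ZT12 (n = 3 each). The others of smallest p were the microRNA genes Mir6988, Mir7672, Mir6911, Mir6912 and Mir6937, short genes whose TPM rest on few reads. The value of Nfil3 was 0.24 with a standard error of 0.43. Limma called 0 genes, with 69 at an unadjusted p under 0.05, and limma-voom called 0, with 112. Camera called 9 lists at its preset correlation and 0 with an estimated one, and 1 fibro-adipogenic gene was called when adjusted over the list alone.

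Over both times together, in an additive model of genotype and time that was added after the first results were seen, the smallest p belonged to Snord47, Trmt112, Cd9, Mrps36, Coa4, Prdx5, Snrpd3, Mir29b-2, Ecscr and A230020J21Rik, all lower in TG. Cd9 had a log2 fold change of -0.37, Prdx5 of -0.73 and the assembly factor Coa4 of -0.28, while Nfil3 had 0.01 with a standard error of 0.21. Limma called 0 genes between genotypes, with 166 at an unadjusted p under 0.05, and limma-voom called 0, with 215. Camera called 10 lists at its preset correlation, with the smallest adjusted p for fast fibre genes (6.8e-05, and adjusted p = 0.0478 with an estimated correlation; median 0.04 against -0.09 over all genes, 11 of 14 higher). Fry gave them a directional adjusted p of 0.876, and without WT ZT0 replicate 2 and TG ZT12 replicate 1 camera did not call them at ZT0 (adjusted p = 0.757, lower) or at ZT12 (0.754). The others were mitochondrial respiration (0.000108 and 0.874), denervation (0.0017 and 0.874), glycolysis (0.00217 and 0.959), macrophage (0.0128 and 0.959), interferon (0.0202 and 0.959), glucocorticoid response (0.0276 and 0.959), erythroid (0.0276 and 0.959), fatty acid oxidation (0.0345 and 0.959) and atrophy (0.0442 and 0.959), each with 0 members called over all genes or over the list alone. With 6 libraries of each genotype the 95% interval of the median gene reached 0.29 to either side on the log2 scale, against 0.42 within 1 time and 0.59 for the interaction. In simulated data, limma found 65.9% of 1.5-fold and 96.1% of 2-fold genotype changes over both times, and 11.2% and 81.0% at ZT0. Those changes were set only in genes of at least 5 TPM, in full on the log2 scale and with independent noise. These shares flatter the test and do not cover lower genes. The deposited tables of the authors, made for each time alone, listed 0 genes past an adjusted p of 0.05 as well, with a smallest adjusted p of 0.9999, and held 5 genes at ZT0 and 4 at ZT12 with a p under 0.05. Of these, Prdx5 came first at ZT0 (log2 fold change -0.51, p = 0.000163 in the authors' table) and the glutathione-degrading enzyme Chac1, named after its values were seen, at ZT12 (-0.30, p = 0.000255).

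Time of day was compared within each genotype to ask how muscle differed between lights on and lights off. In WT muscle, Nr1d1 (chromosome 11, 98767932 to 98775377), a repressor within the clock, rose from 12.9 ± 0.933 TPM at ZT0 to 73.5 ± 9.50 TPM at ZT12 (mean and SD, n = 3 each). Its log2 fold change was 2.41 with a standard error of 0.16 and a limma adjusted p of 3.48e-05. Pdk4 (chromosome 6, 5483351 to 5496278), the kinase that restrains the oxidation of glucose, rose from 29.7 ± 9.38 to 109 ± 27.8 TPM (log2 fold change 1.86, adjusted p = 0.0178). Per2 (chromosome 1, 91415982 to 91459328), another repressor of the clock, fell from 2.77 ± 0.441 to 0.336 ± 0.0434 TPM (log2 fold change -1.49, limma adjusted p = 0.0013). Log2 fold changes from TPM are differences of log2(TPM + 1) throughout. They understate changes of TPM in genes of low level such as Per2, and rank those genes lower than TPM would. Glul (chromosome 1, 153899929 to 153909723), the enzyme that makes glutamine, fell from 136 ± 5.73 to 45.2 ± 3.67 TPM (log2 fold change -1.57, adjusted p = 0.0112). The kinase gene Mylk4 fell from 452 ± 32.8 to 179 ± 29.99 TPM (log2 fold change -1.35, adjusted p = 0.0499).

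Limma called 12 genes in WT, 2 higher and 10 lower at ZT12, and each was so in all 3 libraries against all 3, which chance gives for 10% of genes. The other falls were in Angptl7 (log2 fold change -1.83), Mid1ip1, a regulator of fatty acid synthesis (-1.49), Odf3l2 (-1.48), Arrdc3 (-1.47), the neuropeptide gene Nmb (-1.32), Cys1 (-1.16) and the alcohol dehydrogenase Adh1 (-0.98). Of 17 core clock genes, 1 rose and 1 fell, and 3 and 4 did when adjusted over the list alone. Fry's mixed test gave an adjusted p of 1.27e-11 and its directional test 0.965. The glucocorticoid response list lay lower (median log2 fold change -0.66) with 1 member called, Glul, and 6 when adjusted over the list alone. Camera called it (adjusted p = 8.38e-07, and adjusted p = 0.429 with an estimated correlation). It also called 6 lists that lay higher: extracellular matrix (median 0.38, 9.5e-10 and 0.429), fatty acid oxidation (0.18, 6.12e-08 and 0.552), erythroid markers (3.03, 8.38e-07 and 0.429), slow fibre (0.54, 0.000143 and 0.624), fibro-adipogenic markers (0.24, 0.00015 and 0.429) and mitochondrial respiration (0.05, 0.0289 and 0.999). Adjusted over the list alone, 1 fatty acid oxidation, 5 erythroid and 2 fibro-adipogenic genes were called, and 0 of the other 3 lists. Slow fibre genes had library values of 0.03, 0.91 and -1.79 in WT at ZT0 and 0.34, -0.26 and 0.91 at ZT12, and without WT ZT0 replicate 3 camera did not call them (adjusted p = 0.157). Leaving out single libraries moved the 12 calls to 4 (WT ZT0 replicate 1), 6 (WT ZT0 replicate 3, or WT ZT12 replicate 1 or replicate 2), 5 (WT ZT12 replicate 3), 35 (TG ZT12 replicate 1) and 22 (TG ZT12 replicate 2). Median-of-ratios scaling gave 55 calls (29 higher, 26 lower), upper-quartile scaling 47 (24 and 23), limma-voom 56 (23 and 33), and quantile normalization 52 (25 and 27). The fit without WT ZT0 replicate 2 and TG ZT12 replicate 1 gave 72 (44 and 28), and the haemoglobin level as a covariate 5 (1 and 4). Haemoglobin itself went with time, so this loss of calls cannot be ascribed to blood. With log2 depth as a covariate, chosen after the data were seen, limma called 0 genes changed at ZT12 against ZT0 in WT. At an unadjusted limma p under 0.05 there were 2032 genes, against 484 without the covariate. With it, Nr1d1 had a log2 fold change of 1.87 with a standard error of 0.33, Per2 of -1.85 with 0.33 and Pdk4 of 0.92 with 0.56. Groups took 86.4% of the variance of depth, and the standard error of the median gene went from 0.19 to 0.42.

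**Figure D2:**
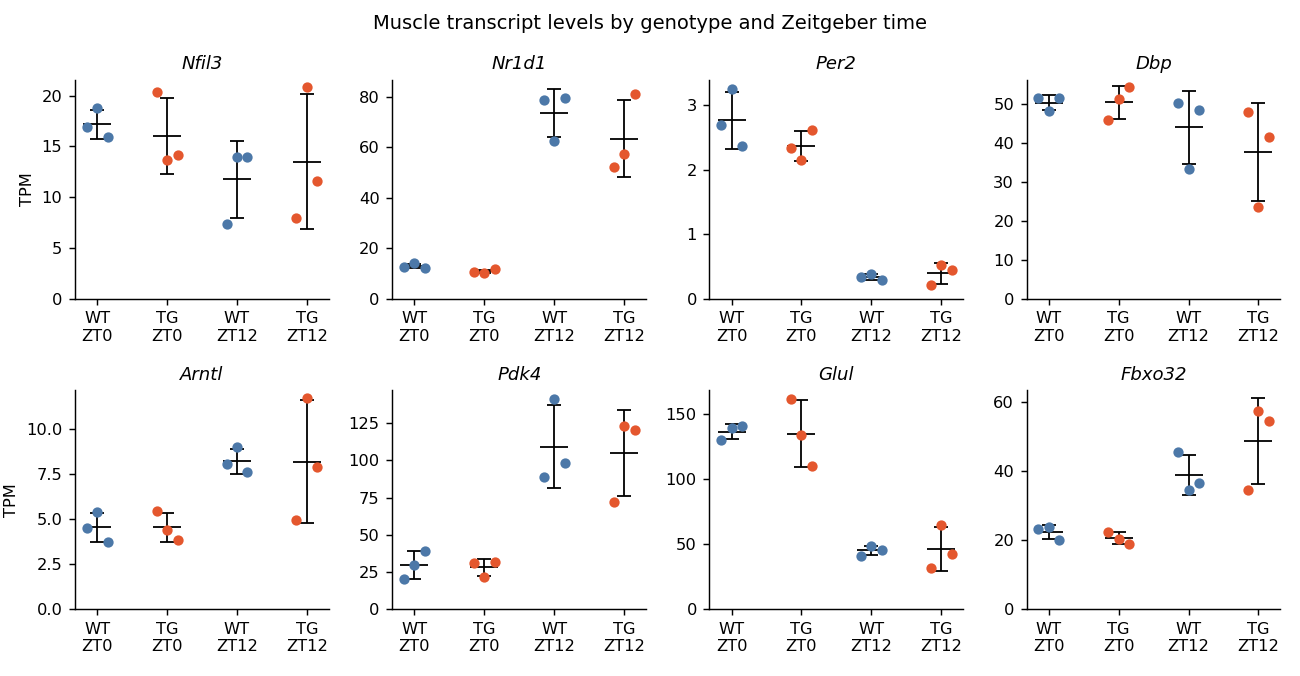
TPM of 8 genes in each library of the 4 groups, with the mean and SD of each group (n = 3): Nfil3, Nr1d1, Per2, Dbp, Arntl, Pdk4, Glul and Fbxo32. Nr1d1 lies at 12.9 and 10.8 TPM at ZT0 and at 73.5 and 63.4 TPM at ZT12 in WT and TG, and Per2 at 2.77 and 2.37 TPM against 0.336 and 0.396 TPM.

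In TG muscle, 10 of the 12 genes called in WT were called as well, and Mylk4 and Odf3l2 were not. Nr1d1 rose from 10.8 ± 0.725 to 63.4 ± 15.4 TPM (n = 3 each; log2 fold change 2.42, standard error 0.16, limma adjusted p = 3.34e-05), Pdk4 from 28.1 ± 5.46 to 105 ± 28.9 TPM (1.84, adjusted p = 0.0162). Per2 fell from 2.37 ± 0.231 to 0.396 ± 0.161 TPM (-1.28, adjusted p = 0.00505). Fbxo32, the muscle ubiquitin ligase atrogin, rose from 20.7 ± 1.68 to 48.8 ± 12.5 TPM (1.17, adjusted p = 0.0212), and the collagen gene Col5a3 rose with it (1.17, adjusted p = 0.036). Arrdc3 fell by 1.80, Arrdc2 by 1.78, Glul by 1.57 and the transcription factor Cebpb by 1.27 on the log2 scale, with limma adjusted p from 4.2e-05 to 0.033. Further falls were in Angptl7 (log2 fold change -2.01), Cys1 (-1.48), the oxygenase Fmo2 (-1.45), the methyltransferase Inmt (-1.45), Mid1ip1 (-1.38), Nmb and Adh1. Limma called 16 genes, 4 higher and 12 lower. Of these, 10 were also called in WT (Per2, Pdk4, Nr1d1, Nmb, Mid1ip1, Glul, Cys1, Arrdc3, Angptl7 and Adh1), where independent lists of these sizes would share 0.0184. The lists are not independent, since 1 fit gave each gene the same standard error in both genotypes, which favours the same genes. Depth also differed between the times in both genotypes. The 10 shared genes thus cannot be weighed against 0.0184. All 18 genes called in either genotype had the same sign in both. Fbxo32, Col5a3, Arrdc2, Fmo2, Inmt and Cebpb passed in TG and not in WT, but the interaction called 0 genes, so that a difference between the genotypes was not shown.

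Of the core clock genes 1 rose and 1 fell in TG. There were 2 and 5 when adjusted over the list alone (fry mixed adjusted p = 2.12e-10, directional adjusted p = 0.997). In the glucocorticoid response list 3 of 17 members fell (Glul, Cebpb and Arrdc2), and 7 when adjusted over the list alone, with a median log2 fold change of -0.48. Camera called this list (adjusted p = 3.53e-14, and adjusted p = 0.276 with an estimated correlation) and 8 more. Core clock (median -0.27, 0.018 and 0.864), Schwann cell (-0.82, 2.41e-07 and 0.43) and smooth muscle markers (-0.36, 0.0193 and 0.864) lay lower. The Schwann cell values were -0.07, 0.54 and 0.34 in the TG ZT0 libraries and -1.27, -0.53 and 0.33 at ZT12, so that TG ZT12 replicate 3 lay within the ZT0 range. Erythroid markers (3.17, 1.89e-08 and 0.311), immediate early genes (0.38, 2.53e-05 and 0.43), fatty acid oxidation (0.10, 0.00142 and 0.864), extracellular matrix (0.18, 0.018 and 0.864) and interferon response (0.26, 0.0397 and 0.864) lay higher. Adjusted over the list alone, 5 erythroid, 4 immediate early and 1 fatty acid oxidation genes were called, and 0 of the Schwann cell, smooth muscle, matrix and interferon genes. Camera was also run without WT ZT0 replicate 2 and TG ZT12 replicate 1. It then did not call core clock (adjusted p = 0.0701), smooth muscle (0.132), erythroid (0.121), immediate early (0.128) or interferon (0.0611). Glucocorticoid response, Schwann cell, fatty acid oxidation and matrix lists kept the call. Single libraries moved the 16 calls to 6 (without TG ZT0 replicate 2), 10 (without TG ZT0 replicate 1 or replicate 3) and 8 (without TG ZT12 replicate 3). The 2 TG groups alone gave 3 calls, median-of-ratios scaling 31 (7 higher, 24 lower), upper-quartile scaling 29 (6 and 23), limma-voom 28 (6 and 22), and quantile normalization 33 (8 and 25). The fit without the 2 libraries named above gave 71 (49 and 22), the haemoglobin covariate 5 (1 and 4), and the depth covariate 2, Nr1d1 (log2 fold change 2.11, adjusted p = 0.00518) and Arrdc3 (-1.92, adjusted p = 0.00518).

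**Figure D3:**
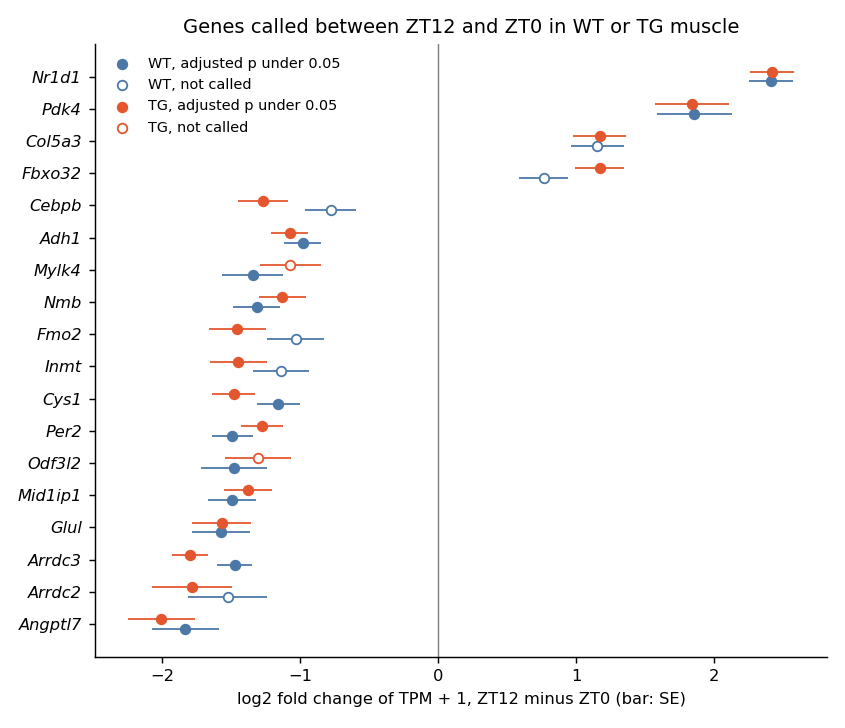
Log2 fold change of ZT12 against ZT0, with its standard error, in WT and in TG muscle for the 18 genes called in either genotype; filled points have an adjusted p under 0.05. All 18 lie on the same side of 0 in both genotypes, from 2.42 for Nr1d1 to -2.01 for Angptl7.

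Over both genotypes, in the additive model, limma called 106 genes between the times, 42 higher and 64 lower at ZT12, of which 96 had all 6 libraries of 1 time above all 6 of the other. Nr1d1 rose from 11.9 ± 1.38 to 68.4 ± 12.7 TPM (mean and SD, n = 6 each; log2 fold change 2.42, adjusted p = 8.12e-08). Pfkfb3, whose product makes the activator of phosphofructokinase, rose from 16.2 ± 8.35 to 59.96 ± 24.9 TPM (1.87, adjusted p = 0.00447). Fos rose by 1.46, the fibrillin gene Fbn1 by 1.25, Col5a3 by 1.16, the nicotinamide riboside kinase Nmrk2 by 1.14, Fbxo32 by 0.97, the stretch-responsive Ankrd1 by 0.94 and Cited4 by 0.93 on the log2 scale. Arrdc3 fell by 1.64, G0s2, an inhibitor of triglyceride lipase, by 1.58, and the mitochondrial carrier Slc25a30 by 1.47. Angptl7, Arrdc2, Glul, Mid1ip1, Odf3l2, Per2 and Cys1 completed the 10 largest falls of log2(TPM + 1) among called genes without overlap of the libraries. Nfil3 stood at 16.6 ± 2.59 and 12.6 ± 4.93 TPM and was not called (log2 fold change -0.43, adjusted p = 0.721).

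In the core clock list 1 gene rose and 4 fell: Per2 (log2 fold change -1.38), Per3 (-0.76), Hlf (-0.75) and Per1 (-0.78); adjusted over the list alone, 5 rose and 7 fell. Arntl (Bmal1), the activator of the clock, stood at 4.55 ± 0.820 and 8.21 ± 0.705 TPM in WT, where its limma adjusted p was 0.556 (log2 fold change 0.74). Over both genotypes it missed the threshold too (log2 fold change 0.70, limma adjusted p = 0.0666). Directions rest on the ZT labels as given: Per2 is known to be high around lights off in mouse peripheral tissues and Arntl around lights on, the opposite of the values here. Nr1d1 is known to be higher at lights off than at lights on, as it was here, and with the 2 times exchanged each direction would turn. In the glucocorticoid response list 6 of 17 fell, among them Glul, Arrdc2, Tsc22d3 (-0.86) and Cebpb (-1.02), and 7 when adjusted over the list alone. The median was -0.63, camera gave an adjusted p of 2.98e-10, the estimated correlation an adjusted p of 0.247, and fry 0.0432. The glycolysis list held 2 rises, Pfkfb3 and the glucose uptake inhibitor Txnip (0.61), and 1 fall, Tbc1d1 (-0.99), with 2 and 4 adjusted over the list alone. Pdk4 was the 1 called member of the fatty acid oxidation list (6 higher and 1 lower adjusted over the list alone), Fbxo32 of the atrophy list (1), Fos of the immediate early list (3 higher, 2 lower), Ddit3 of the integrated stress response (-0.73; 2 higher, 1 lower) and Thrsp of lipid synthesis (-1.16; 2 lower). Of the myogenesis list, Ankrd1 rose and Myod1 fell (-1.19), with 4 and 3 adjusted over the list alone. No member was called of the autophagy (median 0.06; 1 lower adjusted over the list alone), IGF1, GH and insulin signalling (0.00), mitochondrial respiration (0.01), slow fibre (0.39), fast fibre (0.01), denervation (-0.14), interferon (-0.05), heat shock (0.00) and extracellular matrix (0.31) lists. Besides the glucocorticoid list, camera called extracellular matrix (adjusted p = 1.51e-07, and adjusted p = 0.796 with an estimated correlation), fatty acid oxidation (3.73e-07 and 0.796), erythroid (3.1e-09 and 0.247), slow fibre (0.0077 and 0.871; WT ZT0 replicate 3 at -1.79) and Schwann cell (0.00834 and 0.871; TG ZT12 replicate 1 at -1.27) lists. Without TG ZT12 replicate 1 the 106 calls became 160 and without WT ZT12 replicate 2 they became 70. Median-of-ratios scaling gave 233 calls (106 higher, 127 lower), upper-quartile scaling 220 (103 and 117), limma-voom 217 (89 and 128), and quantile normalization 217 (98 and 119). The fit without the 2 libraries gave 464 genes changed at ZT12 against ZT0 over both genotypes (365 and 99), and the haemoglobin covariate, which itself went with time, 24 (6 and 18). With the depth covariate limma called 2, Nr1d1 (log2 fold change 2.12, adjusted p = 0.00303) and Arrdc3 (-1.92, adjusted p = 0.00303), and Pdk4 had 1.32 with a standard error of 0.38. Folds of other named genes moved both ways. Pfkfb3 went to 0.45 with a standard error of 0.44 and Txnip to 0.19 with 0.23, while Cited4 went up to 1.46 with 0.23.

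Markers of other cell types differed between single libraries. The haemoglobin transcript Hba-a1 stood at 449, 1151, 867 and 1311 TPM in replicates 1 and 2 of WT and TG at ZT12, at 49.1 and 42.5 TPM in replicates 3. It stood at 23.8 to 48.7 TPM in the 6 libraries of ZT0. Hba-a1 and Hba-a2 are near-identical paralogs and share reads. Adipocyte transcripts were high in 3 libraries: Adipoq stood at 33.4, 24.6 and 28.3 TPM in WT ZT0 replicate 2, TG ZT0 replicate 2 and TG ZT12 replicate 3. Lymphoid transcripts were high in WT ZT0 replicate 2, where Cd52 stood at 189 TPM against at most 4.78 TPM elsewhere. These genes and the library were singled out after their values were seen. In the additive model the medians of the time effect were 3.11 for the 5 erythroid markers (0 called over all genes, 5 adjusted over the list alone), -0.45 for Schwann cell, -0.26 for smooth muscle, -0.16 for adipocyte, 0.08 for endothelial, -0.03 for macrophage and 0.06 for fibro-adipogenic markers, with 0 called in each. The neutrophil and lymphocyte lists had 0 members in the test and the hepatocyte list 1, Apoa2 (0.28). Of the sex-linked list, 4 Y-linked genes stood above 1 TPM in all 12 libraries, while Xist was at 0 in both deposited log2 tables.

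**Figure D4:**
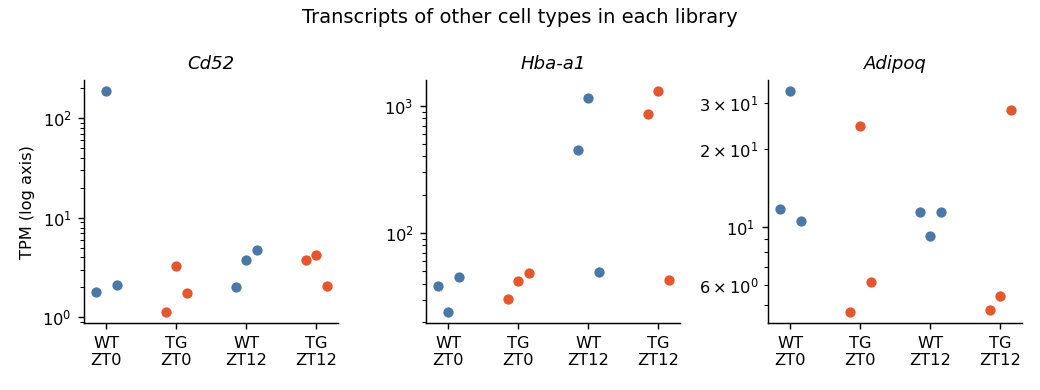
TPM (log axis) of Cd52 (lymphocytes), Hba-a1 (red cells) and Adipoq (fat cells) in each of the 12 libraries. Cd52 is at 189 TPM in WT ZT0 replicate 2 and Hba-a1 at 449 to 1311 TPM in 4 of the 6 ZT12 libraries.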

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

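The tests of explanations in this part and the model of both genotypes and times together were chosen after the results were seen, while the list tests and the splits of the samples were planned.

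The TG effect differed between ZT12 and ZT0 in 9 gene lists by camera at its preset correlation, and in 0 with an estimated correlation or with fry (directional or mixed). The lists with lower values were fibro-adipogenic markers (adjusted p = 2.97e-07 by camera, and adjusted p = 0.229 with an estimated correlation; median -0.43), Schwann cell markers (2.59e-06 and 0.544; -0.74), extracellular matrix (2.98e-05 and 0.758; -0.28), slow fibre (0.00162 and 0.758; -0.24), mitochondrial respiration (0.0017 and 0.758; -0.10), fatty acid oxidation (0.00692 and 0.956; -0.12) and smooth muscle markers (0.0393 and 0.758; -0.18). Immediate early genes (5.19e-06 and 0.544; 0.60) and interferon response genes (6.78e-05 and 0.758; 0.55) had higher values. WT ZT0 replicate 2 stood 1.64 above the mean of the libraries in interferon genes and 0.51 in immediate early genes, and TG ZT12 replicate 1 stood lowest in Schwann cell markers (-1.27). Without these 2 libraries camera called 2 of the 9 lists, slow fibre (adjusted p = 0.000143) and fibro-adipogenic markers (0.000403), with 0.947 for interferon, 0.166 for immediate early and 0.367 for Schwann cell. The slow fibre genes stood at -1.79 in WT ZT0 replicate 3, and without that library alone camera did not call them (adjusted p = 0.524). Of 100 splits of the samples, 46 gave at least 9 lists and the highest of the others gave 17, so that chance cannot be excluded. Within the single comparisons, the 10 splits of 6 samples are too few for a share under 0.05: the real counts of lists were 11 at ZT0, 7 at ZT12, 7 in WT and 9 in TG, and the highest other splits gave 12, 12, 13 and 12, with 2, 7, 7 and 3 splits giving as many as the real one. In each of these 4 comparisons 9 of the other splits called at least 1 list. The estimated correlation within lists was 0.0254 to 0.983, against the preset 0.01.

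For counts of genes, 1 of 100 splits, the real one, gave as many as the 106 genes called between the times over both genotypes. The highest other split gave 0, so a random grouping of the libraries was excluded for this count. In the other splits the time difference adds to the spread, which holds their counts down. The splits do not cover depth, which went with time (r = 0.85) and with which as a covariate most of the 106 calls were lost. For the genotype over both times and for the interaction, limma called 0 genes, with 166 and 69 at an unadjusted p under 0.05 (limma-voom 0 and 0). All 100 splits gave as many, which a count of 0 fixes in advance, and the highest others gave 2 and 1. The 10 splits within 1 time or genotype are too few for a share under 0.05: the real counts were 0 at ZT0, 0 at ZT12, 12 in WT and 16 in TG, the highest others 1, 1, 0 and 1, and 10, 10, 1 and 1 splits gave as many. Where the real count was 0, all splits give as many by definition.

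Rps6ka4, Prdx5, Trmt112 and Esrra, within 92.7 kb of chromosome 19, stood at 0.382 to 0.538 of the WT mean in TG at ZT0, and with Mir5046 and Dnajc4 they made 6 of the 50 genes of smallest genotype p within 1 window of 200 kb, where some overlap or are nested. An effect of the transgene in every TG mouse was contradicted with the labels as given, since for 4 of the 4 genes a TG library of ZT12 lay above a WT library of ZT12, but it stays open because this rests on the labels of WT ZT12 replicate 3 and TG ZT12 replicate 3. An exchange of these 2 labels, picked from the same 4 genes, was tested outside the region: limma called 0 genes there, with 140 of all genes at an unadjusted p under 0.05 against 166 as labelled, while of the other 8 exchanges 2 gave fewer than 140 and the highest gave 580, which decides nothing. A local DNA difference carried by part of the mice is a candidate explanation that also stays open: of 13 protein-coding genes of the deposited TPM table within 300 kb, all on 1 side, 1 (Cox8a) had a ratio under 0.75, and unlisted genes and the other side were not covered (Mir6988 and Fau, among the smallest p at ZT0, start farther out at 6051334 and 6057888). These 3 explanations cannot be told apart without genotypes.

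WT ZT0 replicate 2 stood apart through lymphoid transcripts, with Cd52 at 189 TPM against at most 4.78 TPM elsewhere and Coro1a at 188 against 5.82 TPM. The deposited log2 values, not used in the main comparisons of TPM, held the lymphocyte genes Cd79a and Ptprc 0.35 and 0.20 above the next ZT0 library. Lymphoid tissue in the dissected piece may be the source, since 6 of 6 lymphocyte markers, all outside the tested genes, were highest in this library at ZT0, but the test does not set it apart from lymphocytes of another origin within the muscle. Added red cells were argued against, with Hba-a1 at 0.565 of the median of the other ZT0 libraries. This 1 transcript does not cover white cells of blood. The test of a lower share of muscle fibre RNA alone does not decide. Schwann cell markers had a median of -0.24 against the other WT ZT0 libraries, which differed between themselves by -0.19. Endothelial, smooth muscle and fibro-adipogenic markers had 0.65, 0.40 and 0.12. The design gives no group for this library alone, and no biological explanation was tested.

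Haemoglobin transcripts were high in replicates 1 and 2 of both genotypes at ZT12, with Hba-a1 at 449, 1151, 867 and 1311 TPM. For a change with time of day, 4 of 6 ZT12 libraries lay over 2 times the highest ZT0 library. With no margin, as first set, 5 of 6 did, the last at 49.1 against 48.7 TPM. The margin was chosen after that. Relative to the 12-library mean, the median erythroid marker stood at -1.16 and -1.36 (log2) in the ZT12 replicates 3. It stood at -2.17 to -1.25 at ZT0 and at 1.89 to 3.54 in the other ZT12 libraries. These values argue against a rise at ZT12 in every mouse, while a rise in part of the mice stays open. Blood left in the tissue stays open too: 0 of 5 erythroid markers with the margin, and 2 of 5 without it, were high in other libraries than Hba-a1. Blood cannot be told apart from a change with time of day in part of the mice. Liver RNA as the source in all 4 libraries was argued against, since in WT ZT12 replicate 1, with Hba-a1 at 449 TPM, 6 of 7 hepatocyte markers including Alb had the lowest ZT12 value of the deposited log2 scale, and the largest excess, of Apoa2, was 0.026 on that shrunken scale. In TPM Apoa2 stood at 5.28, 21.7, 5.63 and 10.7 in the 4 libraries and at 3.54 and 3.38 in the other ZT12 libraries, with 3.73 to 6.36 at ZT0, so that liver RNA in the 2 replicates 2 stays open. Liver genes did stand out in the deposited log2 values of WT ZT12 replicate 2 (Alb 0.79 and Apoa1 0.35 above the lowest ZT12 library) and TG ZT12 replicate 2 (0.35 and 0.16), and 7 of 7 hepatocyte markers were highest in the first and second in the other.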

How the results depend on the processing

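Tests with limma-voom on recovered reads, quantile normalization, haemoglobin and depth covariates, the fit without WT ZT0 replicate 2 and TG ZT12 replicate 1, limma on the deposited log2 tables, and list tests without WT ZT0 replicate 3 were chosen after the data were seen, as was the additive model; the other alternatives were planned. Calls below are in the order WT time, TG time and genes changed at ZT12 against ZT0 over both genotypes (12, 16 and 106 as reported): median-of-ratios scaling 55, 31 and 233; upper-quartile scaling 47, 29 and 220; limma-voom on reads recovered from TPM 56, 28 and 217; quantile normalization 52, 33 and 217; the 2 libraries farthest from the rest left out 72, 71 and 464; the mean log2 haemoglobin level as a covariate 5, 5 and 24; log2 depth as a covariate 0, 2 and 2 (with limma, 2032 genes changed at ZT12 against ZT0 in WT, 979 genes changed at ZT12 against ZT0 in TG and 795 over both at an unadjusted p under 0.05). Without depth in the model, 484, 368 and 765 genes had an unadjusted limma p under 0.05. With depth in the model the median standard error went from 0.19 to 0.42 in WT and from 0.13 to 0.28 over both genotypes, since 86.4% of the variance of depth lay between groups. The fold of Nr1d1 over both genotypes went from 2.42 to 2.12. The 2 groups compared alone gave 3 in TG. Haemoglobin also went with time: erythroid markers stood at -2.17 to -1.25 at ZT0 and at 1.89 to 3.54 in 4 of 6 ZT12 libraries. The loss of calls with that covariate therefore cannot be ascribed to blood. The cause of the other moves was not tested. Of the 12 WT calls 11 were shared under median-of-ratios scaling, 12 without the 2 libraries and 5 with the haemoglobin covariate, and of the 106 over both genotypes 97, 106 and 24. Filters, pseudocounts, the replicate block and removal of the 10 highest genes kept these counts within 1.5 times.

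Genotype calls stayed at 0 with limma at ZT0 (117 at an unadjusted p under 0.05; limma-voom 0), except 1 when the 2 groups were compared alone (Prdx5) and 1 without TG ZT12 replicate 3 (Mir6988), so that leaving out single libraries gave 0 to 1. At ZT12 they stayed at 0 (99; limma-voom 0) except 2 with the 2 libraries left out, and 39 and 18 with limma on the deposited log2 table, for all genes with signal and for genes of the TPM test. The interaction and the genotype over both times gave 0 (69 and 166; limma-voom 0 and 0) under all alternatives run. Leaving out single libraries gave 4 (without WT ZT0 replicate 1) to 35 (without TG ZT12 replicate 1) in WT, where WT ZT0 replicate 3 and WT ZT12 replicates 1 and 2 gave 6, WT ZT12 replicate 3 gave 5 and TG ZT12 replicate 2 gave 22; 6 (TG ZT0 replicate 2) to 21 (WT ZT0 replicate 2) in TG, where TG ZT0 replicates 1 and 3 gave 10 and TG ZT12 replicate 3 gave 8; and 70 (WT ZT12 replicate 2) to 160 (TG ZT12 replicate 1) over both genotypes. A group left with 2 libraries shares the spread of the others.

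List tests (11 at ZT0, 7 at ZT12, 7 in WT, 9 in TG, 9 for the interaction) gave 0, 0, 0, 0 and 0 with an estimated inter-gene correlation and with the directional test of fry, and 2, 0, 13, 5 and 2 with the 2 libraries farthest from the rest left out. Without WT ZT0 replicate 3 they gave 11, 8, 7, 9 and 10, with slow fibre not called. The mixed test of fry, for changes either way, did call core clock, glucocorticoid response and myogenesis in WT and TG and fatty acid oxidation in WT. The log2 fold change of Nfil3 between genotypes, never called, changed sign: at ZT0 0.0032 with upper-quartile scaling and 0.00505 with quantile normalization; at ZT12 -0.15 without WT ZT12 replicate 1 and -0.22 without TG ZT12 replicate 2, with 0.43 without TG ZT12 replicate 1; for the interaction -0.03 and -0.10 without WT ZT12 replicate 1 and TG ZT12 replicate 2, with 0.54 without TG ZT12 replicate 1; and over both times -0.05 without TG ZT0 replicate 1, -0.13 without WT ZT12 replicate 1 and -0.16 without TG ZT12 replicate 2, with 0.13 without TG ZT12 replicate 1. Among the named genes of the time comparisons 0 changed sign, and 74 values in WT, 77 in TG and 65 over both genotypes lost the call under an alternative. Scaling by median-of-ratios moved the median gene by 0.0986 at ZT0. Depth differed between the times and, at ZT12, between the genotypes. A read on a 1 kb transcript stood for 0.0411 to 0.0895 TPM, which limits genes near 1 TPM.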

Other observations

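The clock genes in this paragraph were picked after their values were seen, and no tests were run on their timing. In mouse peripheral tissues Per2 transcripts are known to be high around lights off and those of Arntl (Bmal1), its opposite in the clock, around lights on. Here Per2 stood at 2.77 and 2.37 TPM at ZT0 in WT and TG and at 0.336 and 0.396 TPM at ZT12, and Arntl at 4.55 ± 0.820 and 4.56 ± 0.810 TPM at ZT0 against 8.21 ± 0.705 and 8.20 ± 3.40 TPM at ZT12 (n = 3 each). Glul and Tsc22d3, responders to glucocorticoids, which are known to peak near lights off, were lower at ZT12. The data hold 2 times and no reference course, so the phase of the clock cannot be read from them. These values run opposite to the known phase. But Nr1d1, known to be higher at lights off than at lights on, was so here (12.9 and 10.8 TPM at ZT0, 73.5 and 63.4 TPM at ZT12). Exchanged times thus do not account for Nr1d1. Dbp stood at 50.4 and 50.5 TPM at ZT0 and at 44.0 and 37.7 TPM at ZT12, and is not counted for or against an exchange. Whether the ZT0 and ZT12 labels are exchanged, or ZT is counted differently, was not tested and cannot be decided here, and with the times exchanged each direction given for ZT12 against ZT0 would turn.

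Between the 2 genotypes, time effects of the 6131 genes with a mean of at least 5 TPM had a correlation of 0.66 (Spearman 0.45), and genotype effects at the 2 times had 0.17. Genes are not independent, so no p is given.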
